A study of Mus musculus with 16 samples.

How the data were processed

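Polyadenylated RNA of heart ventricles was sequenced from mice with floxed Rbpms alleles, with (cKO) or without (control) a Cre recombinase under the Myh6 promoter, at 8 weeks of age. Libraries were stranded and read from both ends, per the labels' protocols and the series design. The deposited table holds whole-number counts per gene symbol in 1 column per library, which the authors made before deposit. The submitters' processing notes name FastQC 0.11.4, HISAT2 2.0.4, featureCounts 1.6.0 and edgeR 3.30.3 and the builds GRCm38 and mm10, without saying which step used which. The annotation release, the strand setting and the handling of reads with several alignments are not given in the sources used here. Genes with near-identical copies or overlapping genes on the other strand are therefore uncertain, since their reads could be split or shared.

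The table has 54132 rows and 8 library columns, each matched by name to 1 sample label. Of the rows, 24 carry a number where a symbol should stand, as spreadsheet software makes of some names. These were left out of library sizes and tests and held 0.115% to 0.132% of a library's counts. Total counts per library were 20190334 to 24540433, which puts a CPM of 1 at about 20 to 25 reads. Libraries of newborn mice and tables other than the counts were not used here. No GEO label pairs libraries across genotypes, so no block was fitted.

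The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (limma 3.58.1), with genotype as the only term, TMM normalisation, filterByExpr defaults and Benjamini-Hochberg adjustment over all tested genes, and the threshold was an adjusted p under 0.05. Tests were two-sided. Fold changes are cKO over control, and standard errors are the absolute log2 fold change divided by the square root of the F statistic. CPM values are scaled by TMM over the 16051 tested genes, which held at least 99.8% of each library's counts. The common biological coefficient of variation was 0.16. The script was tested on simulated counts of 16051 genes with the real means, library sizes and trended dispersions. For the comparison of cKO with control it recovered 52.2% of genes changed 1.5-fold, 73.1% of those changed 2-fold and 100% of those changed 4-fold, with 4 false calls (2.6%). Only 67, 67 and 66 genes carried these changes, a much smaller share than was called in the real data, so recovery there may differ. The camera step recovered 5 of 5 shifted lists among 30, with 0 false calls. Simulated genes varied independently and the lists were random, so this could not show false calls that arise from correlated genes.

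Gene lists were 42 sets for cardiomyocyte function, metabolism, signalling, stress responses and the other cell types of the ventricle, written before the data were examined. Of 1423 members 1419 have a row in the table. Each list was tested with camera at a preset correlation of 0.01, and adjusted p-values cover all 42 lists. With an estimated correlation 2 lists passed, resting fibroblast markers and ion channels and gap junctions. The directional fry test, which asks whether genes of a list move one way on balance, passed for 18. Counts of members that rose or fell use the adjusted p over all genes. The second count is adjusted over the list alone.

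The rule for named genes was fixed beforehand. It takes Rbpms, Rbpms2, Nppa, Nppb, Myh6, Myh7 and Acta1, then the 10 largest rises and 10 largest falls among called genes with a mean CPM of at least 1 and no overlap between groups. From each list it takes up to 4 members with the smallest adjusted p. Some of the genes it takes are not reported here. Positions, gene types, lengths and GC content are from GENCODE release M21 (GRCm38), matched by symbol, and 53067 symbols (98.0%) were found. Replicate pairs were checked for duplicate deposits, and the chi-square per degree of freedom between libraries of 1 genotype was 7.09 to 31.2, so none were alike. Counts of Xist and of 4 Y-linked genes matched the sex label of all 8 libraries.

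Alternatives were DESeq2 1.42.0 size factors, upper-quartile factors and total counts for scaling, no filter and a stricter filter on low counts, DESeq2, limma-voom and the edgeR exact test, robust dispersions, sex as a covariate, each library left out, males only, no mitochondrially encoded genes, and an adjusted p under 0.01. A fit with 1 surrogate variable (sva 3.50.0) was added later. Means of log2 CPM over lists used a prior count of 2 and exact permutation of the 8 libraries.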

Results

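The data are gene-level read counts from the ventricles of 8-week-old mice. Rbpms encodes an RNA-binding protein, and the study removed it from heart muscle cells with a floxed Rbpms allele and a Cre recombinase driven by the Myh6 promoter, which is active in cardiomyocytes. The cardiac knockout (cKO) libraries come from such mice, and the control libraries come from mice with the floxed allele and no Cre. There were 4 libraries per genotype, 3 from males and 1 from a female (replicate 3 in both), and the totals ran from 20190334 to 24540433 counts per library. The labels give each library its own sex and do not say whether tissue was pooled, so the p-values measure the spread between these libraries. Newborn ventricles of both genotypes also belong to the series and were not analysed here. The comparison asks how ventricular gene expression differs when cardiomyocytes lack Rbpms, a gene the series title links to contraction and RNA splicing; transcript isoforms were not analysed here.

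Rbpms, the targeted gene (chromosome 8, 33782643 to 33929863 in GRCm38), fell from 159.7 ± 42.8 CPM (depth-scaled counts, mean ± SD, n = 4) in controls to 31.8 ± 5.82 in cKO ventricles. Its log2 fold change was -2.33 with a standard error of 0.20 (adjusted p = 3.54e-05), a 5.02-fold lower level. Control libraries ranged from 101.6 to 193.2 CPM and cKO libraries from 26.9 to 38.8, so no library went against its genotype label. In an exact two-sided permutation test of the CPM values p was 0.0286, the smallest value that 4 against 4 libraries can give. Ventricle also holds cells in which the Cre driver is silent, and the labels do not say which exon is floxed, so the remaining counts do not measure how complete the deletion was. Its paralog Rbpms2 (chromosome 9, 65629648 to 65660528) fell as well, from 43.7 ± 6.88 to 22.9 ± 4.12 CPM (log2 fold change -0.93 ± 0.15 SE, adjusted p = 0.0011).

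Nppa, Nppb, Myh7 and Acta1, which mark strain on cardiomyocytes and were named beforehand, were strongly raised, and the wider list of such genes is given below. Nppa and Nppb, neighbouring genes on chromosome 4 that encode the atrial and B-type natriuretic peptides, rose 7.17-fold (60.9 ± 29.3 to 436 ± 69.4 CPM) and 6.33-fold (45.9 ± 18.8 to 290.6 ± 94.1 CPM). Myh7, the slow myosin heavy chain that is the main form in the fetal mouse ventricle, rose 5.03-fold from 563 ± 268 to 2834 ± 1654 CPM. Acta1, skeletal alpha-actin, rose 7.52-fold from 284 ± 287 to 2136 ± 265 CPM, and 14.9-fold without control replicate 4, whose 705.5 CPM was the highest control value. Skeletal muscle genes, a list that holds Acta1, moved with this library, with a median log2 fold change of 0.17 in all libraries (camera adjusted p = 0.505) and 1.29 without it (adjusted p = 5.79e-05). Actin genes resemble each other closely, so reads of Acta1 could be split with its paralogs. Myh6, the adult fast myosin heavy chain, measured 19800.1 ± 2879 CPM in controls and 15603 ± 1798 in cKO, a log2 fold change of -0.34 ± 0.13 SE that missed the threshold (adjusted p = 0.0952). Myh6 passed without control replicate 2 (adjusted p = 0.0331), with DESeq2 (0.0253) and with the edgeR exact test (0.0479).

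**Figure D1:**
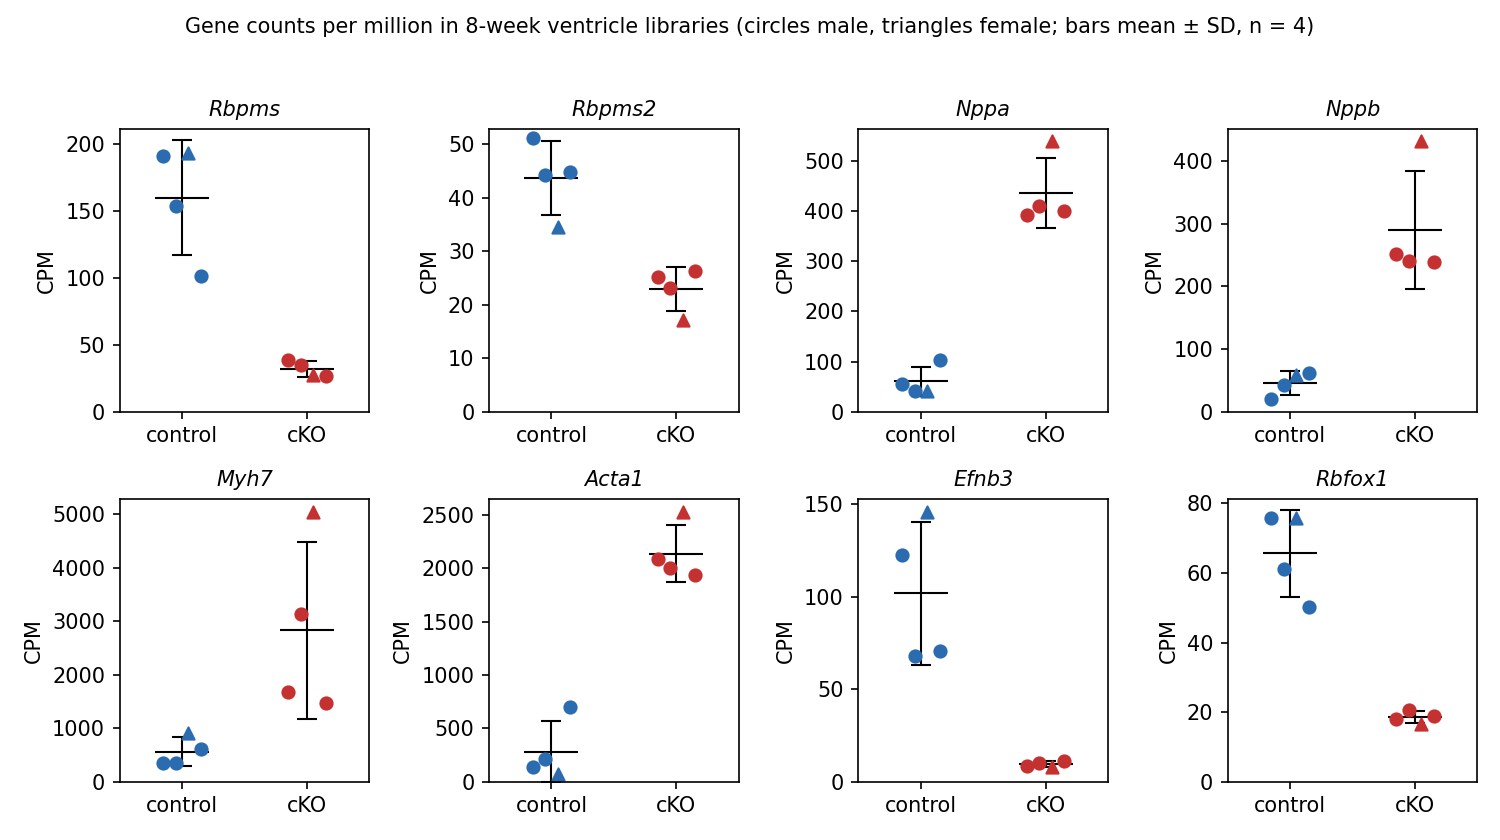
CPM of 8 genes in each 8-week ventricle library, with circles for males, triangles for females and bars for the mean ± SD of the 4 libraries of a genotype. Rbpms, Rbpms2, Efnb3 and Rbfox1 were lower in every cKO library than in every control library, and Nppa, Nppb, Myh7 and Acta1 were higher in every cKO library than in every control library.

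Of 16051 genes tested, 1548 rose and 1547 fell in cKO ventricles at an adjusted p under 0.05 by edgeR's quasi-likelihood test, 19.3% of those tested. At least 2-fold changes were found for 528 of the genes that rose and 246 of those that fell. The groups did not overlap in CPM for 23.5% of genes, against 2.86% by chance. With total counts as the only scaling, 66.1% of the called genes were higher, while TMM gave nearly equal numbers in both directions. The first principal component held 39.1% of the variance and separated the genotypes, the second (18.4%) separated both female libraries from the 6 male ones, and the third (12.8%) set control replicate 4 apart. Control replicate 4 also had the highest share of mitochondrially encoded counts (11.8%, against 8.04% to 10.1% in the other libraries), and 2819 genes passed without it. The cKO libraries had counts in 24246 to 25216 genes and the controls in 22986 to 23720.

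Among genes that rose with separate groups, large changes were found in Psca, Tnmd, 2610028H24Rik, Chodl, Dusp26, Edn3, Lrp8, Kcnj14 and Serpinb1c. Psca, a small surface protein, had 3 counts in all controls and 196 in all cKO libraries, a depth-scaled ratio of 58.4 (95% exact interval 19.7 to 286, counting error only). Its log2 fold change was 5.66, and 6.55 without control replicate 3. Tnmd, a glycoprotein of tendon and ligament, had 4 counts in 1 control library, none in the others and 50 to 61 in each cKO library, a ratio of 50.5 (95% exact interval 19.5 to 187). Its log2 fold change was 5.50, and without control replicate 2, the library with those counts, no control level was measured and the fitted 8.76 rests on the prior count. The uncharacterised gene 2610028H24Rik was 30.6-fold higher (log2 fold change 4.94 ± 0.39 SE), from a low control level of 0.22 ± 0.17 CPM, and 47.1-fold higher without control replicate 1. Chodl, a lectin-domain membrane protein, rose 23.4-fold from a low 0.26 ± 0.22 to 6.17 ± 3.02 CPM, and the phosphatase gene Dusp26 rose 12.8-fold to 15.2 ± 6.55 CPM. Edn3, an endothelin peptide, rose 12.6-fold from 1.45 ± 1.34 to 17.8 ± 5.05 CPM, and 22.6-fold without control replicate 4. Lrp8, a lipoprotein receptor family member, rose 11.2-fold to 15.4 ± 3.77 CPM, and Kcnj14, an inward rectifier potassium channel, also 11.2-fold to 14.8 ± 5.74 CPM. Serpinb1c rose 10.4-fold. It belongs to a family of close copies, and its rise was 6.22-fold without cKO replicate 3.

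Among genes that fell with separate groups and a mean CPM of at least 1, the largest falls were in Wdr72, Efnb3, BC023105, Tmprss13, Gm10635, Zfand4, Prlr, Cabcoco1, Lrrc4b and H2-Q6. Efnb3, a membrane-bound ephrin ligand on chromosome 11 (69554092 to 69560205), fell 10.5-fold from 102 ± 38.8 to 9.73 ± 1.48 CPM (adjusted p = 2.47e-05). Wdr72 fell 22.9-fold from 2.04 ± 0.88 to 0.083 ± 0.068 CPM, a level of few reads, so the size of its fall is uncertain. Prlr, the prolactin receptor, fell 6.06-fold from 13.6 ± 3.87 to 2.25 ± 0.49 CPM. Cabcoco1 fell 6.02-fold from 15.7 ± 3.01 CPM, Zfand4 6.09-fold from 8.70 ± 2.24 CPM, and Lrrc4b 5.72-fold to 1.92 ± 1.10 CPM. Tmprss13, a membrane serine protease, fell 7.54-fold to 0.29 ± 0.13 CPM, and Gm10635, a long intergenic noncoding RNA, fell 6.34-fold. BC023105 is annotated as a processed pseudogene and H2-Q6 is one of several nearly identical class I genes, so their counts are uncertain. BC023105 had a log2 fold change of -3.12 ± 0.68 SE, -2.26 without control replicate 2, and missed the threshold with limma-voom (adjusted p = 0.0691). H2-Q6 had a log2 fold change of -2.44 ± 0.67 SE, and its adjusted p rose from 0.0242 to between 0.0526 and 0.0747 without control replicate 2 or 4 or cKO replicate 1 or 4, and to 0.115 with robust dispersions.

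Of the 20 fetal and stress genes of cardiomyocytes, 11 rose and 1 fell (12 and 2 adjusted over the list alone). The median log2 fold change was 1.08 (camera adjusted p = 1.04e-07, adjusted p = 0.149 with an estimated correlation). Besides those named above, Xirp2, an actin-binding protein of the Z-disc and intercalated disc, rose 2.88-fold from 1029 ± 229 to 2963 ± 1007 CPM. Ankrd23, a titin-associated ankyrin repeat protein, rose 3.10-fold. Atp2a2, the calcium pump of the sarcoplasmic reticulum, was the member that fell, with a log2 fold change of -0.49. Here and below, members that moved against most of their list were named after their values were seen.

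Sarcomere filament genes went both ways. Of 38 tested, 8 rose and 5 fell (9 and 5 adjusted over the list alone), the mean log2 fold change was 0.25, the median -0.01, and the list was not called (camera adjusted p = 0.697). Mybpc2, the fast skeletal form of myosin-binding protein C, rose 6.09-fold from 30.6 ± 13.7 to 186 ± 31.2 CPM, and Myom3, an M-band protein, rose 3.54-fold. Fhod3, a formin that organises sarcomeric actin, fell 1.59-fold from 604 ± 29.0 to 379 ± 45.2 CPM, and the thin filament capping gene Tmod1 fell 1.45-fold. Without control replicate 2, or without cKO replicate 1 or 2, 5 sarcomere genes rose, and the list was called higher without control replicate 4 (adjusted p = 0.0455). Among 44 Z-disc and costamere genes, 12 rose and 7 fell (15 and 7 adjusted over the list alone). Fhl1, a LIM-domain protein, rose 2.79-fold from 136 ± 24.1 to 380.5 ± 104 CPM, while its relative Fhl2 fell 2.54-fold from 1065 ± 90.3 to 419 ± 97.8 CPM. Pdlim3 rose with a log2 fold change of 0.81 and the actin-associated Palld fell with -0.54. The Z-disc list was called higher (median 0.09, camera adjusted p = 0.0384), with adjusted p = 0.772 with an estimated correlation. It was not called without control replicate 1, 2 or 3 (adjusted p = 0.0784, 0.158 and 0.0541), when members held by other lists were left out (0.953), with the stricter filter (0.0538) or in the directional fry test (0.134). Its median was 0.06 without control replicate 1, 0.05 without control replicate 2, 0.18 without control replicate 4 and 0.04 without cKO replicate 3. Without cKO replicate 1, 4 of its members fell.

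The list of genes for ion channels and gap junctions fell as a group, though among its connexin genes only Gja3 fell. Of 42 tested, 24 fell and 1 rose (27 and 1 adjusted over the list alone), with a median log2 fold change of -0.42 (camera adjusted p = 7.18e-14, adjusted p = 0.0198 with an estimated correlation). Hcn4, the pacemaker channel, fell 3.81-fold from 28.1 ± 7.43 to 7.36 ± 1.59 CPM. Kcnip2, a subunit of the transient outward potassium channel, fell 2.26-fold from 268 ± 17.1 to 119 ± 24.1 CPM. Abcc9, the sulfonylurea receptor subunit of ATP-sensitive potassium channels, fell 2.04-fold from 1016 ± 127 to 499 ± 19.2 CPM, and the connexin gene Gja3 fell 2.25-fold. The connexin genes Gja1, Gja5 and Gjc1 did not pass, with log2 fold changes of 0.01, 0.09 and 0.12.

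Calcium handling genes were lower by smaller amounts. Of 35 tested, 10 fell and 2 rose (10 and 3 adjusted over the list alone), with a median log2 fold change of -0.11 (camera adjusted p = 0.00772, adjusted p = 0.228 with an estimated correlation). Slc8a1, the sodium-calcium exchanger, fell 2.16-fold from 299 ± 34.8 to 139 ± 20.1 CPM, and Ryr2, the calcium release channel, fell from 3645 ± 301 to 2278 ± 276 CPM (log2 fold change -0.68). Camk2a and the calcium channel subunit Cacnb2 fell with log2 fold changes of -0.87 and -0.80. Casq1 and Stim1 rose with 1.88 and 0.39, and Casq1 missed the threshold with robust dispersions (adjusted p = 0.0541). The list was not called when members held by other lists were left out (adjusted p = 0.351), and its median was -0.06 without control replicate 4.

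Adrenergic and cyclic AMP signalling genes and intercalated disc genes were also called lower. In the first list 12 of 35 fell and 2 rose (14 and 3 adjusted over the list alone; median -0.13, camera adjusted p = 0.019, adjusted p = 0.149 with an estimated correlation). Adra1a, an alpha-1 adrenergic receptor, fell 2.67-fold from 49.5 ± 12.0 to 18.6 ± 5.90 CPM, Adrb1, the beta-1 receptor, fell 1.59-fold, and Pde3a fell 1.45-fold. Grk5, a receptor kinase, and Arrb1 rose with log2 fold changes of 1.08 and 0.38, and Arrb1 missed the threshold without cKO replicate 1 (adjusted p = 0.0533). The median of this list was -0.23 without control replicate 3. Of 21 intercalated disc genes, 5 fell and 1 rose, as when adjusted over the list alone (median -0.07, camera adjusted p = 0.0357, adjusted p = 0.313 with an estimated correlation). In males alone 3 disc genes fell. Ctnna3, alpha-T-catenin, fell 2.60-fold from 53.6 ± 7.64 to 20.6 ± 3.72 CPM. Cxadr and the desmosomal cadherin gene Dsg2 fell 1.91-fold and 1.43-fold, and Nrap rose 1.54-fold. The disc list was not called without control replicate 4 (median -0.04, adjusted p = 0.102) or cKO replicate 4 (0.0515), with total counts only (0.11) or with the stricter filter (0.0538), and its median was -0.11 without control replicate 2, -0.10 without cKO replicate 1, -0.12 without cKO replicate 3 and 0.01 with total counts only.

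Among the lists called higher, extracellular matrix and fibrosis genes had the highest median log2 fold change and the smallest camera adjusted p at the preset correlation. With an estimated correlation the matrix list did not pass, while the resting fibroblast list given below did. Of 69 tested, 54 rose and 1 fell (56 and 2 adjusted over the list alone), and the median log2 fold change was 1.18 (camera adjusted p = 1.62e-44, adjusted p = 0.0585 with an estimated correlation). Cilp, a matrix protein first described in cartilage, rose 7.53-fold from 13.7 ± 3.38 to 103 ± 30.6 CPM. Bgn, the proteoglycan biglycan, rose 2.43-fold from 266 ± 23.3 to 647 ± 88.5 CPM. Mfap5, a microfibril protein, and Sfrp1, a secreted Wnt antagonist, rose 2.99-fold and 2.29-fold. Ltbp1, a latent TGF-beta binding protein, was the member that fell (log2 fold change -0.75).

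Markers of resting fibroblasts rose too, in 19 of 24 tested with 0 falling (21 and 0 adjusted over the list alone). Their median log2 fold change was 0.68 (camera adjusted p = 1.65e-19, adjusted p = 0.0198 with an estimated correlation). Mfap4 rose 4.08-fold from 13.9 ± 2.39 to 56.5 ± 12.4 CPM, and Dpt and the growth factor receptor gene Pdgfra rose 1.81-fold and 1.78-fold.

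Markers of other cells in the ventricle were measured beside these. Of 31 endothelial markers 3 rose, among them Npr3 and Plvap (log2 fold changes 0.90 and 0.78), and 3 fell, among them Prox1 (-0.48), with 3 and 4 adjusted over the list alone. The endothelial median was -0.08 and the list was not called (camera adjusted p = 0.703), and 1 endothelial marker fell without control replicate 1 or 4 or cKO replicate 3. Of 23 smooth muscle and pericyte markers 3 rose, including Itga8 (0.99), and 4 fell, including Smtn (-0.79), with the same numbers adjusted over the list alone. Their mean and median were 0.04 and 0.02, the test pointed lower, and the list was not called (camera adjusted p = 0.548). The balance of smooth muscle markers turned to 5 higher and 2 lower without cKO replicate 3 and 5 and 3 in males alone. It was 2 and 2 without control replicate 1, 1 and 2 without control replicate 2 or cKO replicate 1, 1 and 3 without cKO replicate 2 and 1 and 4 without cKO replicate 4. Of 32 macrophage and monocyte markers 6 rose and 0 fell, as when adjusted over the list alone (median 0.29, camera adjusted p = 0.0118, adjusted p = 0.786 with an estimated correlation). Lgals3, galectin-3, rose 3.83-fold to 7.48 ± 4.01 CPM and the scavenger receptor gene Cd163 1.52-fold, and the macrophage list was not called without control replicate 3 (median 0.17, adjusted p = 0.334), in males alone (0.151) or in the directional fry test (0.224). Without control replicate 3, in males alone and with no filter on low counts 4 macrophage markers fell, and 2 fell without cKO replicate 2. In all libraries Cd74, H2-Aa, H2-Ab1 and H2-Eb1 had log2 fold changes of -0.91, -0.81, -0.96 and -1.03 and did not pass. The mean log2 CPM of the macrophage markers differed by 0.33 between cKO and control (exact permutation p = 0.2, n = 4 per genotype). Of 28 complement and acute inflammation genes 9 rose and 0 fell (13 and 1 adjusted over the list alone; median 0.59, camera adjusted p = 3.6e-05, adjusted p = 0.0554 with an estimated correlation). Ptgs2, a prostaglandin synthase, rose 2.79-fold to 5.42 ± 1.03 CPM, and Tlr4 rose 1.71-fold.

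Epicardial and mesothelial markers rose in 6 of 19 and fell in 1 (7 and 1 adjusted over the list alone; median 0.30, camera adjusted p = 0.00337, adjusted p = 0.301 with an estimated correlation). Krt8, a keratin of simple epithelia, rose 9.51-fold to 4.92 ± 2.03 CPM and Aldh1a1 1.74-fold, and the median was 0.15 without control replicate 4. Of the members that rose, Dcn is also in the fibroblast list and Clu in the atrial list. Members that did not pass went both ways, from -0.47 (Efemp1) to 0.46 (Tbx18) in log2 fold change. Among them were Msln (-0.05), Upk3b (-0.08) and Wt1 (0.17). Ezr was the member that fell (log2 fold change -0.36), and its adjusted p lay between 0.0745 and 0.0912 without control replicate 2 or 4 or cKO replicate 1, 2 or 3. Schwann cell and neuron markers rose in 6 of 17 and fell in 2 (9 and 2 adjusted over the list alone; median 0.54, camera adjusted p = 0.00988, adjusted p = 0.136 with an estimated correlation). Pmp22, a myelin protein, rose with a log2 fold change of 0.68, while Dbh, the noradrenaline-synthesising enzyme, fell 4.62-fold from 3.41 ± 0.71 CPM and Hand2, a transcription factor also expressed in heart, fell with a log2 fold change of -0.48.

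**Figure D2:**
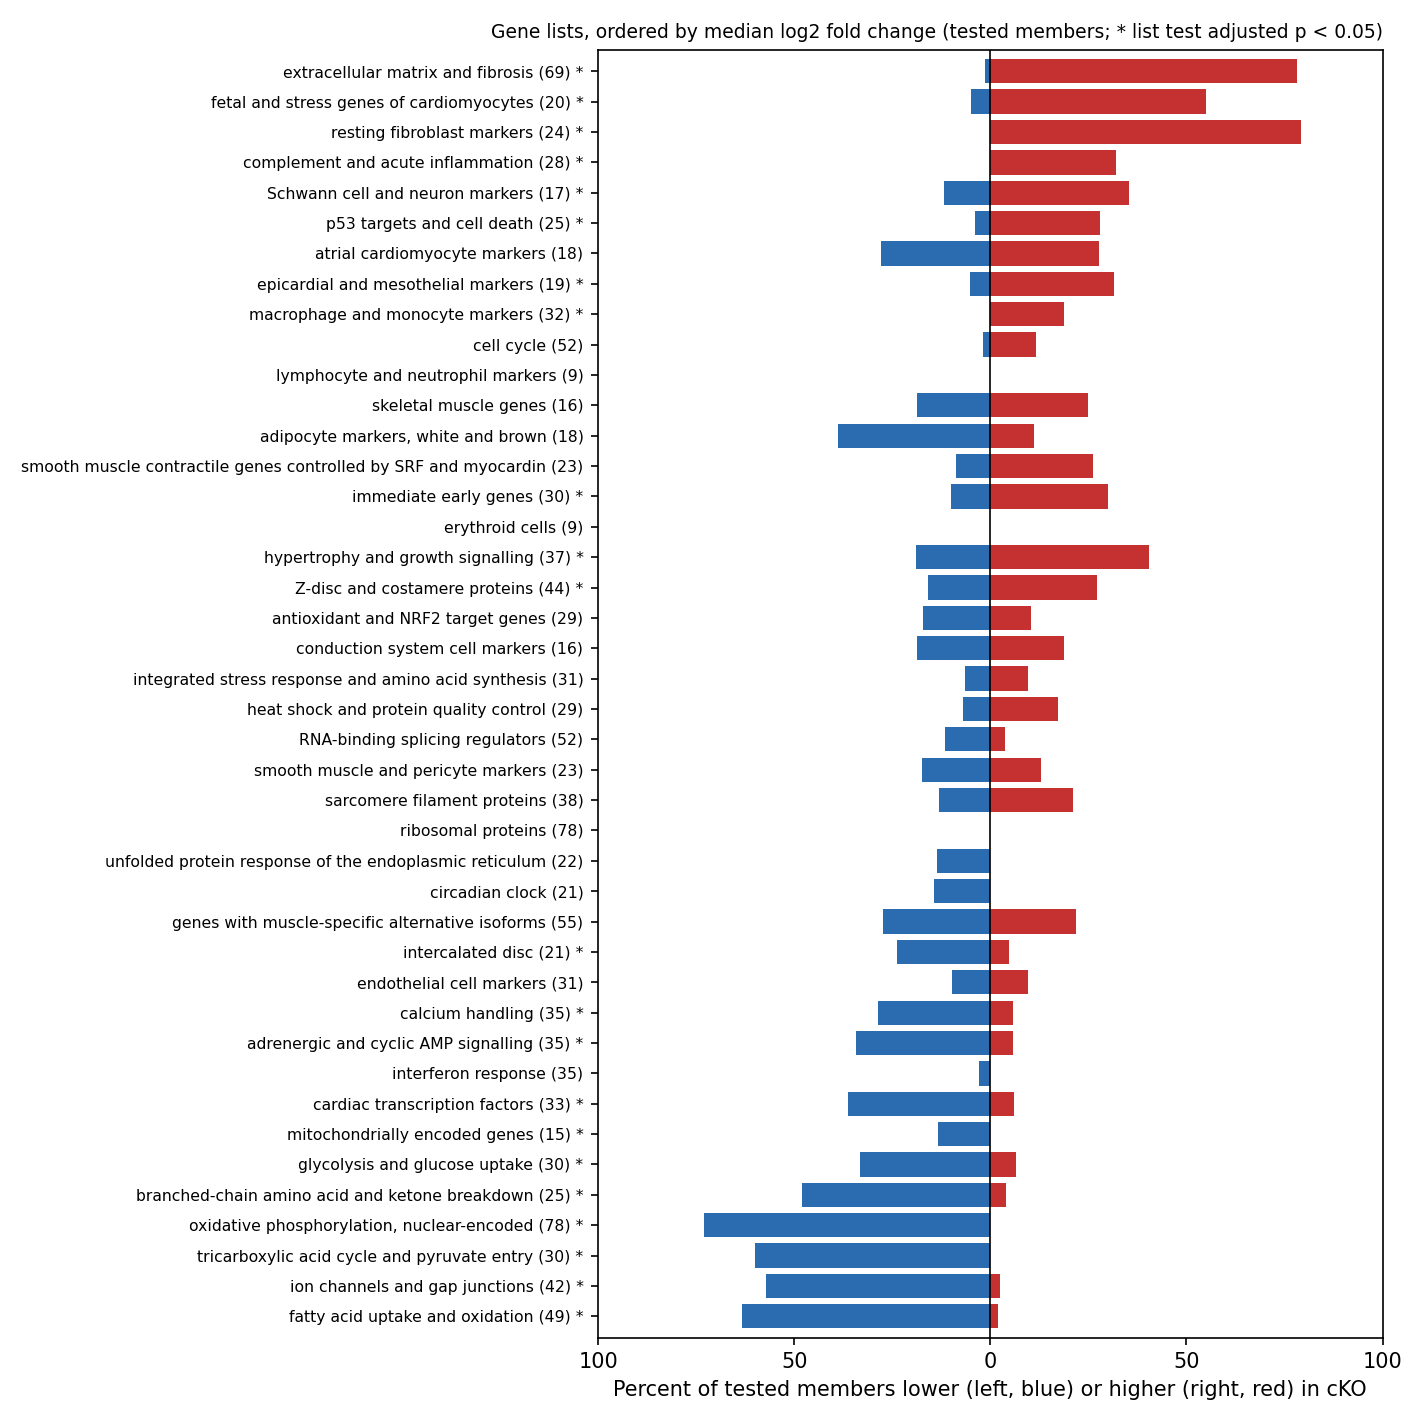
Percent of the tested members of each of 42 gene lists that were lower (blue, to the left) or higher (red, to the right) in cKO ventricle at an adjusted p under 0.05, ordered by median log2 fold change, with an asterisk where the camera list test passed at the preset correlation. In the extracellular matrix list 54 of 69 members were higher, and in the oxidative phosphorylation list 57 of 78 were lower.

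Genes of mitochondrial energy production fell broadly and by modest amounts. Of 78 nuclear-encoded oxidative phosphorylation genes, 57 fell and 0 rose (68 and 1 adjusted over the list alone), with a median log2 fold change of -0.36 (camera adjusted p = 2.87e-20, adjusted p = 0.276 with an estimated correlation). Complex I subunit genes Ndufb10, Ndufa8 and Ndufs7 fell with log2 fold changes of -0.48, -0.55 and -0.50, and Cox5b of complex IV fell 1.35-fold from 260.2 ± 9.24 to 193 ± 9.89 CPM. With the 3 male libraries of each genotype alone 34 fell. Of 49 genes of fatty acid uptake and oxidation, 31 fell and 1 rose (35 and 1 adjusted over the list alone; median -0.50, camera adjusted p = 5.02e-18, adjusted p = 0.121 with an estimated correlation). Acsl1, which activates long-chain fatty acids, fell 1.64-fold from 1440.2 ± 32.5 to 880.0 ± 69.0 CPM, the carnitine transporter Slc22a5 fell 1.86-fold, and Pdk2 fell 1.76-fold. Ucp2, a mitochondrial inner membrane carrier, was the member that rose, 3.01-fold to 411 ± 42.6 CPM.

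Of 30 genes of the tricarboxylic acid cycle and pyruvate entry, 18 fell and 0 rose (26 and 0 adjusted over the list alone; median -0.39, camera adjusted p = 7.18e-14, adjusted p = 0.219 with an estimated correlation). Pdp2, a phosphatase that activates pyruvate dehydrogenase, fell 2.31-fold from 71.9 ± 8.47 to 31.1 ± 3.33 CPM, and Idh3a and Suclg1 fell 1.57-fold and 1.51-fold. Glycolysis and glucose uptake genes fell in 10 of 30 and rose in 2 (16 and 3 adjusted over the list alone; median -0.28, camera adjusted p = 1.35e-05, adjusted p = 0.219 with an estimated correlation). Pfkl, a phosphofructokinase, fell 2.25-fold from 114 ± 6.40 to 50.7 ± 1.89 CPM, Pdk1 fell 1.82-fold and Pfkfb1 4.68-fold, while Pfkp and the monocarboxylate transporter Slc16a1 rose with log2 fold changes of 0.46 and 0.38. Of 25 genes of branched-chain amino acid and ketone breakdown, 12 fell and 1 rose (16 and 1 adjusted over the list alone; median -0.35, camera adjusted p = 2.83e-08, adjusted p = 0.245 with an estimated correlation). Bckdhb and Mccc2 fell 2.06-fold and 1.86-fold, and Bcat1 rose with a log2 fold change of 1.13.

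Mitochondrially encoded genes were less clear. Of 15 tested, mt-Rnr1 and mt-Rnr2, the ribosomal RNAs of the mitochondrion, fell with log2 fold changes of -0.67 and -0.55, and none rose, as when adjusted over the list alone. The list was called lower (median -0.23, camera adjusted p = 0.0198, adjusted p = 0.802 with an estimated correlation), but not without control replicate 4 (median -0.10, adjusted p = 0.191) or cKO replicate 3 (0.0617) or in the directional fry test (0.287). The adjusted p of mt-Rnr2 was 0.0513, 0.0703 and 0.0797 without control replicate 1, cKO replicate 1 and cKO replicate 3. Over 17 abundant sarcomere genes outside the fetal and stress list, the mean log2 CPM differed by -0.12 between cKO and control (exact two-sided permutation p = 0.114, n = 4 per genotype). The same mean over oxidative phosphorylation genes differed by -0.35 (exact permutation p = 0.0286, n = 4 per genotype). Ribosomal protein genes served as a reference group, and 0 of 78 passed the gene test (0 also adjusted over the list alone; mean 0.002, median -0.01, camera adjusted p = 0.814).

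**Figure D3:**
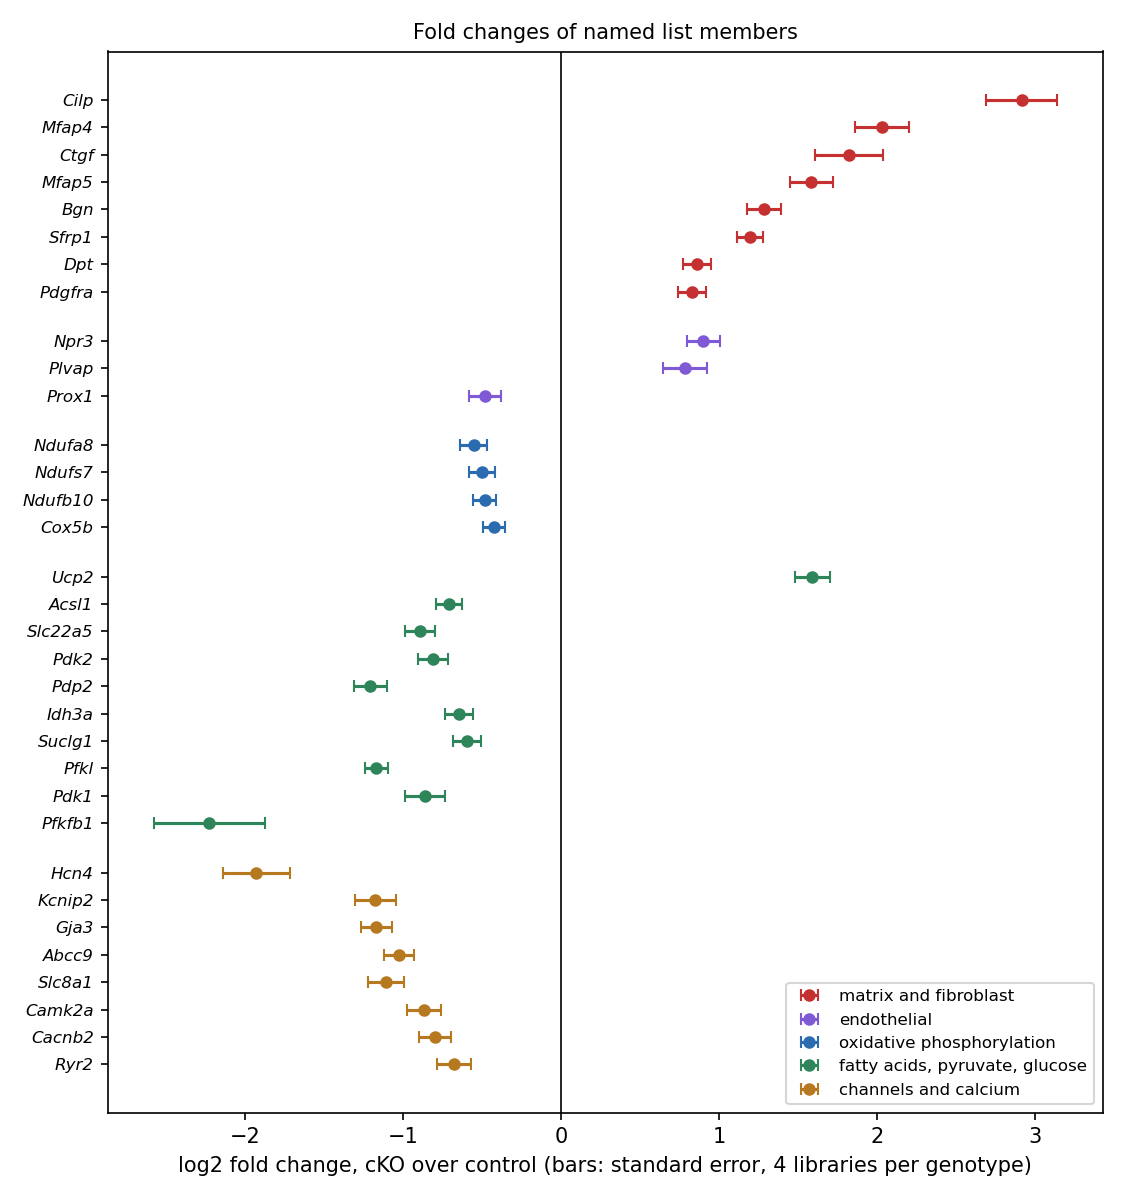
Log2 fold change of named list members in cKO over control ventricle, with bars for the standard error from 4 libraries per genotype and colours for the gene group. The matrix and fibroblast genes shown lay between 0.83 and 2.91, the oxidative phosphorylation genes between -0.55 and -0.43, and the genes of channels and calcium handling between -1.93 and -0.68. These members were taken for their small adjusted p, and others of their lists lay outside these ranges, such as Casq1 (1.88) and Ltbp1, which fell.

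RNA-binding splicing regulators were tested as a list that includes Rbpms itself, the gene the design removed. Of 52 tested, 6 fell, Rbpms and Rbpms2 included, and 2 rose (6 and 1 adjusted over the list alone). Without control replicate 3, 6 of 53 rose, and with total counts only 5 rose. The mean was -0.06, the median 0.02, and the list was not called (camera adjusted p = 0.448), though it was called lower without control replicate 4 (0.0429). Rbfox1, a splicing factor of muscle and brain, fell 3.54-fold from 65.7 ± 12.5 to 18.6 ± 1.73 CPM, and Rbm38 fell 1.46-fold. Raver2 and Celf1 fell with log2 fold changes of -1.32 and -0.26, and Celf2 and Fxr1 rose with 0.40 and 0.28. Celf1 missed the threshold without cKO replicate 2 (adjusted p = 0.0588), with total counts only (0.125) and in males alone (0.081), and Fxr1 without any single library other than control replicate 3 (0.0633 to 0.114). Of 55 genes known for muscle-specific alternative isoforms, 15 fell and 12 rose at the level of whole-gene counts (16 and 13 adjusted over the list alone; median -0.07, camera adjusted p = 0.197), and the list was called lower with no filter on low counts (median -0.08, adjusted p = 0.0259). Of these, 37 also belong to other lists, and its named members Slc8a1, Pdlim3, Cacnb2 and Palld are given above.

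Cardiac transcription factor genes were called lower. Of 33 tested, 12 fell and 2 rose (13 and 2 adjusted over the list alone; median -0.17, camera adjusted p = 3.6e-05, adjusted p = 0.219 with an estimated correlation). Rxrg, a retinoid X receptor, fell 2.45-fold from 52.1 ± 1.49 to 21.3 ± 1.28 CPM. Gata6, Myocd and Mef2a fell 1.54-fold, 1.54-fold and 1.38-fold, and Irx5 and Yap1 rose with log2 fold changes of 0.54 and 0.34. Of 37 hypertrophy and growth signalling genes, 15 rose and 7 fell (17 and 9 adjusted over the list alone; median 0.14, camera adjusted p = 0.019, adjusted p = 0.228 with an estimated correlation). Igf1, insulin-like growth factor 1, rose 2.33-fold from 29.4 ± 5.98 to 68.3 ± 6.98 CPM and Akt1, a kinase downstream of its receptor, fell 1.58-fold. The median of this list was 0.22 without control replicate 3. Immediate early genes rose in 9 of 30 and fell in 3 (10 and 4 adjusted over the list alone; median 0.16, camera adjusted p = 0.037, adjusted p = 0.595 with an estimated correlation). Egr3 and Myc rose 3.72-fold and 2.17-fold from under 4 CPM, 5 members rose without cKO replicate 1, 1 fell without cKO replicate 2, and the list was not called without control replicate 3 or 4 or cKO replicate 1 or 3 (adjusted p = 0.0642, 0.142, 0.0605 and 0.0847), in males alone (0.116), when members held by other lists were left out (0.0763) or in the directional fry test (0.0754). Targets of p53 and cell death genes rose in 7 of 25 and fell in 1 (10 and 1 adjusted over the list alone; median 0.36, camera adjusted p = 0.0144, adjusted p = 0.342 with an estimated correlation). Phlda3 and Plk2 rose 2.05-fold and 1.65-fold, 4 members rose without control replicate 1 and 2 without cKO replicate 1. Ccng1 was the member that fell (log2 fold change -0.43), with adjusted p between 0.0513 and 0.0822 without control replicate 2 or 4 or any single cKO replicate.

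Called genes were spread over the genome. Among chromosomes 1 to 19 and X the smallest adjusted p of Fisher's exact test was 0.356, for chromosome 11. Within 5 Mb of Rbpms 8 of 28 other tested genes passed, 28.6% against 19.3% of all genes (Fisher's exact p = 0.229). None of 444 windows of 5 Mb was enriched at an adjusted p under 0.05, and the smallest adjusted p was 0.0503, for a window each on chromosome 14 (65000001 to 70000000, 17 of 36 genes) and chromosome 8 (90000001 to 95000000, 22 of 54 genes). Only the cKO mice carried Cre, so an effect of Cre or of sequence near the transgene cannot be told from an effect of the deletion.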

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

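In groups of 4 libraries, Dixon's ratio (the gap of an extreme library to its neighbour over the whole range) passed its 95% limit for 18 of 278 groups of named genes and library measures, against 13.9 expected, since chance passes about 1 group in 20. The explanation tests on fibroblast and matrix genes were chosen only after the result was seen.

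In cKO libraries, replicate 3, the only female cKO library, was the outlying one in 8 of 9 cases. It was the highest for Nppa (ratio 0.879, 540 CPM against 411 for the next library), Nppb (0.939, 432 against 251), Chodl (0.906, 10.7 against 5.03), Serpinb1c (0.925, 23.3 against 6.91), Ankrd23 (0.913) and Lgals3 (0.978, 13.5 against 5.55). It was the lowest for Gm10635 (0.873) and Ltbp1 (0.84). With 1 female per genotype, sex and the single library cannot be told apart. Zfand4 was lowest in cKO replicate 1 (0.981). Control replicate 2 stood apart for Tnmd (ratio 1, the only control library with counts), Kcnip2 (0.839, lowest), Ucp2 (0.843, highest), Pfkl (0.857, lowest) and Prox1 (0.845, lowest). Control replicate 4 was highest for Edn3 (0.873, 3.45 CPM against 0.952) and Myocd (0.831), control replicate 1 for Adrb1 (0.926), and control replicate 3 for Pdk1 (0.889).

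Of 35 splits of the 8 libraries into 4 and 4, only 1, the real one, called as many genes (3095), and the highest of the others called 12.

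Fibroblast and matrix genes rose together. A lower share of cardiomyocytes would raise markers of every other cell type alike, but resting fibroblast markers rose by 0.719 more log2 CPM than endothelial markers (exact permutation p = 0.0286, n = 4 per genotype), whose own change was -0.01. More fibroblasts with unchanged expression per cell would raise both lists alike only if both drew the same share of their reads from fibroblasts. Matrix genes rose by 0.489 more than fibroblast markers (exact permutation p = 0.0286, n = 4 per genotype), but that share was not measured, so this cannot decide. A lower share of cardiomyocytes alone does not account for the flat endothelial markers, if these are specific. Smooth muscle markers changed by 0.03 log2 CPM. The Schwann cell, epicardial and macrophage lists had median log2 fold changes of 0.54, 0.30 and 0.29, so a part in the pattern stays possible. Cell numbers and expression per cell were not measured here, so the cause stays open, an effect of Cre itself included, and counts from single nuclei with a Cre-only control would be the test.

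Nuclear-encoded mitochondrial energy genes fell together. With fewer cardiomyocytes in the tissue, abundant sarcomere genes would fall as far if their expression per cell stayed unchanged. Oxidative phosphorylation genes changed by -0.226 log2 CPM relative to 17 such genes (exact permutation p = 0.0286, n = 4 per genotype). Sarcomere expression per cell was not measured, so a lower share of cardiomyocytes is not excluded. A bias of gene length and GC content was tested by taking off a fitted trend over all genes. The list median was -0.346 after it and -0.359 before. The fitted trend does not account for the fall. A lower share of cardiomyocytes with unchanged sarcomere expression per cell does not account for the whole fall either. The cause of the fall stays open, since expression within cardiomyocytes was not measured here. Counts from sorted cardiomyocytes soon after the deletion, with a Cre-only control, would be the test.

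Rbpms2 fell together with its paralog Rbpms. Reads shared between them would lower both counts, but their annotated transcripts share 0 stretches of 30 bases. A true fall of Rbpms2 RNA is then the hypothesis left open, and reads misplaced through shorter matches were not tested.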

How the results depend on the processing

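All alternatives but 1 were chosen before the data were examined. The fit with 1 surrogate variable was chosen after seeing the data and called 1766 genes higher and 1767 lower. The threshold of 0.01 left 808 higher and 817 lower, by its own construction. With total counts only, 1992 genes were higher and 1021 lower, with a shift of the median gene of 0.083. This setting drops the TMM factors, which were 1.009 to 1.041 in cKO libraries and 0.906 to 1.014 in controls. Dropping them shifts genes upward in cKO, and why the factors differ was not tested. With an estimated inter-gene correlation 1 list was called higher and 1 lower, against 11 and 11, and the cause was not tested. Leaving out 1 library at a time gave 1129 to 1458 genes higher, 1093 to 1418 lower, 454 to 527 higher and 212 to 270 lower by at least 2-fold, and 8 to 12 lists higher and 10 to 12 lower. DESeq2 called 1702 higher and 1807 lower, limma-voom 1534 and 1533, the edgeR exact test 1670 and 1611, sex as a covariate 1758 and 1754, and males only 1214 and 1166. No gene called in both the main test and an alternative changed sign. Of 133 named genes past the threshold of 0.05, 9 lost the call in at least 1 alternative at that threshold and none changed sign. Of 22 lists called, 16 kept the call at 0.05 in the alternatives run for lists, the estimated correlation and fry aside. Named genes and lists were not counted at 0.01, and lists were not run with DESeq2, limma-voom or the exact test. The fits with both ages and the genotype by age interaction were not run, since newborn libraries were not analysed here. Totals of 20190334 to 24540433 counts per library and 4 libraries per genotype limit detection. In the simulation 52.2% of 1.5-fold changes were found, but a much smaller share of genes changed there than the 19.3% called here.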

Other observations

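Several further lists were not called and their moving members went both ways. Cell cycle genes rose in 6 of 52 and fell in 1 (5 and 1 adjusted over the list alone; median 0.25, camera adjusted p = 0.0888). Cenpf, a kinetochore protein, fell 3.14-fold from 66.1 ± 23.9 CPM (SD, n = 4) while Ccnd2, cyclin D2, rose 1.44-fold, and the list passed without control replicate 1 or 2 or cKO replicate 2 or 3 (adjusted p = 0.0196, 0.0108, 0.00766 and 0.0378) and with no filter on low counts (0.0367). Without cKO replicate 1 or 4, 3 members of that list rose. Skeletal muscle genes rose in 4 of 16 and fell in 3, as when adjusted over the list alone (median 0.17, camera adjusted p = 0.505). Without control replicate 4 the skeletal median was 1.29, 7 members rose and the list was called higher (adjusted p = 5.79e-05). Ckm, muscle creatine kinase, fell 1.76-fold from 927 ± 141 to 527.4 ± 38.0 CPM. Atrial markers rose in 5 of 18 and fell in 5 (6 and 5 adjusted over the list alone; median 0.32, camera adjusted p = 0.448), with Nppa among the rises and Kcnj3, an atrial potassium channel, falling 2.95-fold. Conduction system markers rose in 3 of 16 and fell in 3 (3 and 4 adjusted over the list alone; mean -0.19, median 0.03, camera adjusted p = 0.679). Smooth muscle genes controlled by SRF and myocardin rose in 6 of 23 and fell in 2, as when adjusted over the list alone (median 0.17, camera adjusted p = 0.129; 0.00759 without cKO replicate 3, 0.0272 in males alone and 0.0443 with no filter on low counts), with Ctgf up 3.54-fold and Tpm2 up 2.59-fold, and 3 members rose without cKO replicate 1. Adipocyte markers fell in 7 of 18 and rose in 2, as when adjusted over the list alone (mean 0.27, median 0.17, test direction lower, camera adjusted p = 0.287), and Slc36a2 and Lipe fell 2.74-fold and 1.75-fold. Of those that fell, Cox7a1 and Cox8b are also in the oxidative phosphorylation list and Acacb in the fatty acid list. Adipoq, Cidec, Plin1 and Cfd, at low levels, had log2 fold changes of 1.25 to 1.32 and did not pass. The balance turned in males alone, where 8 adipocyte markers rose and 5 fell, and was 5 and 6 without control replicate 3 and 8 and 7 of 22 with no filter on low counts.

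Stress response lists moved little. Heat shock genes rose in 5 of 29 and fell in 2, as when adjusted over the list alone (median 0.02, camera adjusted p = 0.332), with Hsp90aa1 up 1.87-fold from 106 ± 17.6 to 198 ± 40.9 CPM, and 0 members fell without cKO replicate 1 or 2. With total counts only 8 heat shock genes rose. Genes of the unfolded protein response fell in 3 of 22, as when adjusted over the list alone (median -0.02, camera adjusted p = 0.37), with the chaperone gene Hspa5 down with a log2 fold change of -0.49. Integrated stress response genes rose in 3 of 31 and fell in 2, as when adjusted over the list alone (median 0.02, camera adjusted p = 0.697), and 1 rose without control replicate 1 or cKO replicate 1 or 3. Aldh1l2 fell 2.98-fold and Shmt2 fell with a log2 fold change of -0.395. Nupr1, Gdf15 and Atf4 rose with log2 fold changes of 1.325, 2.46 and 0.45, and the groups overlapped for Gdf15. Antioxidant genes rose in 3 of 29 and fell in 5 (4 and 5 adjusted over the list alone; median 0.06, camera adjusted p = 0.798), with Sod2 down 1.39-fold and Gpx3 up 1.70-fold. Without cKO replicate 1 or in males alone 3 antioxidant genes fell, and 2 fell with total counts only, while 1 rose without control replicate 1 and 5 without control replicate 2. Circadian clock genes fell in 3 of 21, as when adjusted over the list alone (mean -0.01, median -0.05, camera adjusted p = 0.548). With any single library left out other than control replicate 2 or cKO replicate 2, 0 or 1 clock gene fell, and 2 rose without control replicate 1. In lymphocyte and neutrophil markers 0 of 9 passed (median 0.22, camera adjusted p = 0.679) and in erythroid markers 0 of 9 (median 0.16, camera adjusted p = 0.679). Interferon response genes fell in 1 of 35 (0 adjusted over the list alone; median -0.16, camera adjusted p = 0.185; 0.0194, 0.0117 and 0.0249 without control replicate 1 or 3 or cKO replicate 4, and 0.0243 with no filter on low counts). Without control replicate 1 or 3, 3 and 4 of them fell.

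Some values were picked after they were seen. Among 20 interferon-inducible GTPase genes of the IRG and GBP families, 8 fell and 0 rose (median log2 fold change -0.55). Iigp1 measured 128 CPM in controls and 58.5 in cKO, and Igtp 31.3 and 10.7, and these families hold similar copies. Of 5 H2-Q genes 2 fell.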
